A study of Ulva lactuca with 7 samples.

How the data were processed

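Thalli of Ulva lactuca were sampled once in each of 7 conditions, and RNA was extracted with a commercial plant kit and made into libraries with a TruSeq-type kit, per the labels' protocols. The submitters' processing notes name cutadapt, Bowtie2 and DESeq without versions, roles or order. The assembler, the counting program and the annotation are not given in the sources used here. The identifiers have the form that de novo assemblies use, a gene part and an isoform part, and the gene part is called the assembled gene here.

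The authors' expression table gives, per the file headers, a read count and an FPKM value for each transcript in each library, with the transcript's length and its GC content in percent. The counts are whole numbers and were used as deposited. The deposited FPKM values imply library totals of 23202937 to 37934762 reads, while the counts sum to 2.56 to 2.91 times these totals, so a read that fits several isoforms appears to be counted on each of them. The largest isoform of each assembled gene alone sums to 0.863 to 0.899 of the implied totals. Of the 10455 assembled genes with at least 2 transcripts past the filter, 75.3% had a second transcript within 20% of the count of the first. Counts of transcripts are therefore not counts of independent genes, and near-identical isoforms and paralogs may share reads. FPKM values served for this check and no test.

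The authors' comparison tables give, per the file headers, a fold change (ratio), a p-value and an adjusted p-value for 1 library against 1, besides the counts of both libraries. They also give a signal per library that the authors made by dividing the count by a size factor of that table. The counts in these tables equal those of the expression table in all 137594 transcripts. Status labels in the authors' tables follow an unadjusted p-value of at most 0.05 and at least 100 counts in 1 of both libraries, a rule found here by comparison and met by 137594 transcripts of each table. How the authors adjusted the p-values is not given in the sources used here. The p-values in these tables are given to 5 decimals.

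Groups were taken from the treatment labels. The title of the control library begins with 24, as the titles of the libraries dried for 24 h do, while its treatment label says that it was always submerged, and the treatment label was followed. The chi-square statistic per transcript between libraries ranged from 151 to 723, so no pair was the same library deposited again.

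Transcripts with a mean count of at least 10 over the 7 libraries were compared, 66046 in number, with a median length of 1759 nt. Counts were scaled by trimmed means (TMM) in edgeR 4.0.16 under R 4.3.3. Log2 ratios between single libraries used edgeR's log2 CPM with a prior count of 2, and a 4-fold difference was the threshold for the number of transcripts higher or lower. Ratios of the transcripts named have exact (Clopper-Pearson) 95% intervals from the 2 counts, and a count of 0 is set at a floor of 3 counts, which corresponds to 0.0323 to 0.0434 CPM after scaling over the libraries. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules and no replicate shows the spread between thalli.

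Resubmergence was tested with edgeR's quasi-likelihood test on the 6 libraries other than the control, with the drying period as a block, because the authors' own tables pair each dried library with the resubmerged library of the same period. Desiccation and resubmergence were each tested against the control on all 7 libraries with the state as the term of the model. The periods stand in for replicates of a state, so the residual, with 2 and 4 degrees of freedom, holds differences between periods as well as library noise. P-values measure only the spread between these samples, and the single control is assumed to vary like the other libraries. The biological coefficient of variation was 50.8% in the first model and 63.8% in the second. Calls were made at a Benjamini-Hochberg adjusted p under 0.05. DESeq2 1.42.0 and limma 3.58.1 (voom) were run on the same designs. Adjusted p-values that DESeq2 left empty were not counted as calls.

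The model was tested on simulated counts for the 66046 transcripts with 200 of them changed, 100 by 4-fold and 100 by 16-fold. With a low spread (dispersion 0.02) the model recovered 100% and 100% of the 4-fold and 16-fold changes in the resubmergence design and 99% and 100% in the desiccation design. With the fitted spread it recovered 33% and 94% in the first and 2% and 37% in the second. Here each transcript had the spread that the trend gives for its level, and a changed transcript had the same fold in each period. Recovery in the real libraries, where both vary and transcripts with lower counts are tested too, can be lower. Unchanged transcripts called were 6 and 7 with the low spread and 2 and 1 with the fitted spread, in this order of designs. For the comparisons across periods, 20 sets of 7 unchanged libraries were drawn from the mean levels and each transcript's own spread in the model of state alone. That spread holds differences between periods, so the simulated numbers may be too high.

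Transcripts are named by a rule: the 2 with the highest and the 2 with the lowest log2 ratio in the period where that ratio is smallest in size, for desiccation against the control and for resubmergence against desiccation, 1 per assembled gene. The rule also covered annotated products, but the files do not pair transcripts with names, so the parts of it that need names, and the gene lists fixed for photosynthesis, stress proteins, metabolism and other organisms, were not used here. Any other transcript named was chosen after its values were seen. The comparisons, tests, filters, thresholds and the rule for names were set before the data were examined. GC bands, the removal of GC trends, the on or off sets and the tests on 1 transcript per assembled gene were added later.

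The GC trend of a library was a lowess curve (span 0.3) of its log2 CPM, centred over the libraries, on transcript GC content. It was fitted without the transcripts found in the 72 h desiccated library alone, and a fit on all transcripts was also made. A set found in 1 library alone, or on in some libraries and off in others, needed at least 50 counts in each library where it is on and a level at least 20 times that of each library where it is off. Random lists for the percentiles were matched in 20 bins of mean expression and drawn 10000 times. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for ratios, intervals and plots. Alternatives covered the scaling, the tool, the filter, the prior count, the fold threshold, the block, and leaving out each drying period.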

Results

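The series followed transcript levels in thalli, the flat blades, of Ulva lactuca, a green seaweed of the intertidal zone, while they dried and after they returned to water. RNA of 7 conditions was sequenced with 1 library per condition. The control thalli stayed under seawater, 3 sets of thalli were dried at 20% moisture for 24, 36 or 72 h, and 3 more sets were put back into autoclaved seawater for 1 h after the same drying periods. No condition had a replicate library, so ratios between single libraries are given with an interval for counting error and no p-value. The total count was 64315136 in the control, 97270080, 89184889 and 63782317 after 24, 36 and 72 h of desiccation, and 89178193, 85041447 and 78585833 in the libraries resubmerged after these periods. The counts cover 137594 assembled transcripts in 90206 assembled genes, and 66046 transcripts in 22319 of these genes reached a mean count of 10 and entered the comparisons. The files do not pair transcripts with gene names or products, so no gene group by function is reported and transcripts are given by their assembly identifiers.

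The series asks which transcripts respond to drying. Transcript c31946_g1_i11 (5402 nt, 48.6% GC) had 0 counts in the control and 3383, 3026 and 1749 counts after 24, 36 and 72 h of desiccation. Against a floor of 3 counts in the control these are 981, 858 and 569-fold higher. The lower limits of the 95% counting intervals are 797, 697 and 462-fold. Transcript c21645_g1_i1 (1130 nt, 45.5% GC) had 1 count in the control and 4245, 4408 and 2391 counts in the desiccated libraries, ratios of 3693 (95% counting interval 663 to 145910), 3748 (672 to 148060) and 2334 (418 to 92216). On the lower side, c34706_g3_i1 (1703 nt, 51.3% GC) had 22172 counts in the control and 5, 5 and 2 after 24, 36 and 72 h, so that the control was 5097-fold (2184 to 15698), 5216-fold (2235 to 16065) and 11358-fold (3144 to 93793) above them. Transcript c33025_g1_i1 (1648 nt, 48.6% GC) had 38318 counts in the control and 12, 10 and 8 in the desiccated libraries, which put the control 3670-fold (2101 to 7103), 4507-fold (2451 to 9399) and 4907-fold (2490 to 11367) above them. None of these 4 transcripts passed the test across the 3 periods, with adjusted p-values of 0.403, 0.387, 0.366 and 0.366 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In the libraries resubmerged after 24, 36 and 72 h, c31946_g1_i11 had 1785, 1525 and 0 counts, c21645_g1_i1 had 2719, 1483 and 4, c34706_g3_i1 had 0, 7079 and 27727, and c33025_g1_i1 had 1, 31991 and 39791. All 4 belong to sets of on or off transcripts that part the control and the library resubmerged after 72 h from other libraries, so drying is not the only difference that these ratios can hold.

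**Figure D1:**
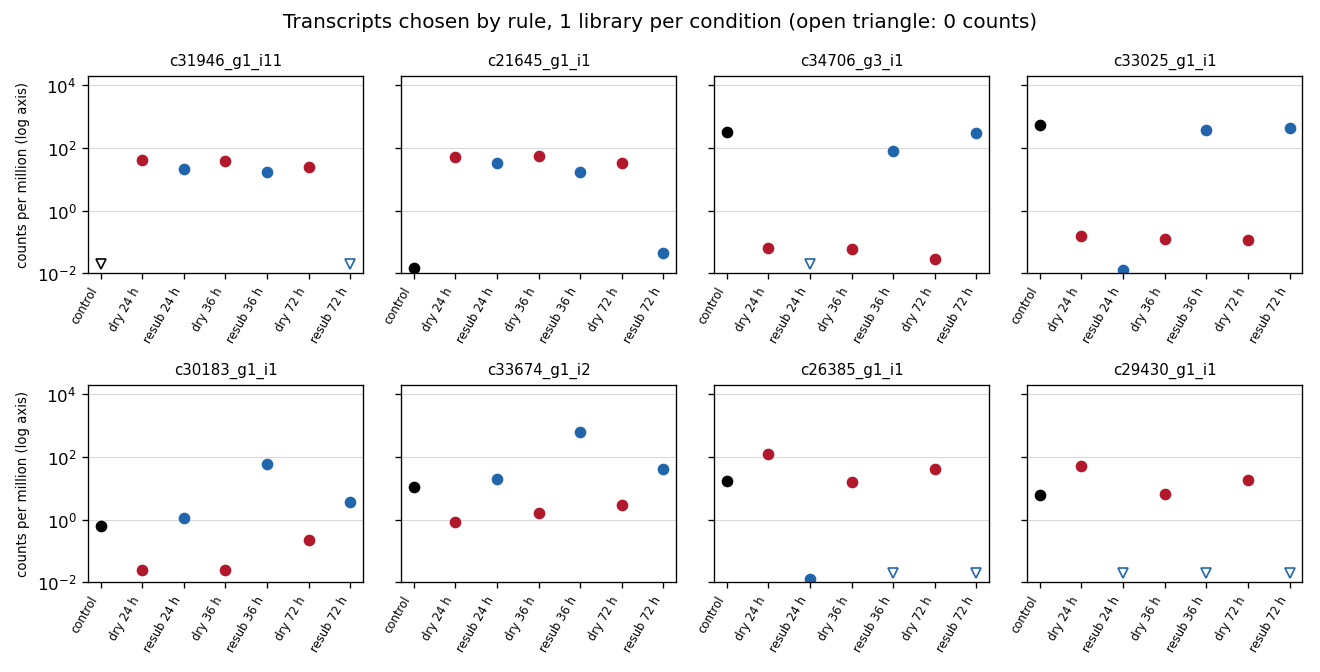
Scaled counts (CPM) on a log axis for the 8 transcripts chosen by rule, 1 point per library: control in black, desiccated in red and resubmerged in blue. An open triangle at a fixed height near the bottom marks 0 counts and can lie above the point of a library with 1 count. c31946_g1_i11 is at 0 counts in the control and in the library resubmerged after 72 h, and c26385_g1_i1 has 1, 0 and 0 counts in the 3 resubmerged libraries.

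More transcripts were at least 4-fold above the control than at least 4-fold below it in each desiccated library. After 24 h, 6470 transcripts were higher and 4282 lower, after 36 h 5610 were higher and 3954 lower, and after 72 h 9352 were higher and 3988 lower. With scaling by total counts in place of trimmed means the split turned to 4825 higher and 5998 lower at 24 h and to 4668 higher and 5048 lower at 36 h. That scaling moved the median log2 ratio of all transcripts from 0.10 to -0.24 at 24 h and from 0.03 to -0.16 at 36 h. Of the 9352 transcripts higher after 72 h, 1342 belonged to a set found in that library alone, and 8010 remained without that set.

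Across the 3 desiccated libraries, 2593 transcripts in 1269 assembled genes were at least 4-fold above the control each time and 1201 transcripts in 627 genes were at least 4-fold below it each time. The 3 comparisons share 1 control library. Simulated unchanged libraries, in which 3 libraries share 1 control that was simulated too, gave a mean of 1074.5 higher and 478 lower over 20 simulations. Independent lists of these sizes would share 77.8 and 15.5. With 1 control the control could not be split, so part of the excess may come from it. Pearson's r of the log2 ratios across transcripts, which are not independent replicates, was 0.74 between 24 and 36 h, 0.56 between 24 and 72 h and 0.64 between 36 and 72 h, where simulated unchanged libraries gave 0.50 for each pair. The covariances of these pairs were 1.98, 1.85 and 1.97, and exceeded the simulated covariances of 1.00, 1.00 and 1.00 by 0.98, 0.85 and 0.97.

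In the test of desiccation, which took the 3 periods as replicates of the dry state against the 1 control, edgeR called 0 of 66046 transcripts, with a smallest adjusted p of 0.284. An unadjusted p under 0.05 was found for 7627 transcripts, 4155 higher and 3472 lower, where evenly spread p-values would give 3302. Transcripts are not independent and anything particular to the 1 control shifts many of them together, so the excess need not come from drying. DESeq2 called 3403 transcripts, 2615 higher and 788 lower, and limma-voom called 0. On simulated counts with the spread fitted to these libraries, the edgeR test recovered 2% of transcripts changed 4-fold and 37% of those changed 16-fold, so a count of 0 does not exclude changes of these sizes. The simulated fold was the same in each period and the changed transcripts had counts well above the filter, which can overstate recovery. The transcripts named above, with larger ratios in each period, were not called.

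**Figure D2:**
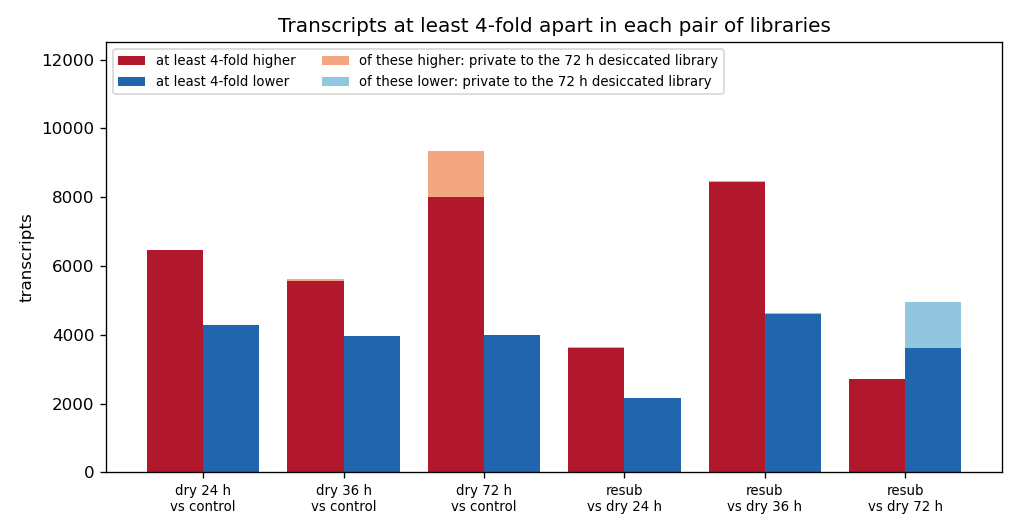
Number of transcripts at least 4-fold higher (red) or lower (blue) in each pair of libraries, 3 desiccated libraries against the control and 3 resubmerged libraries against the desiccated library of the same period; the lighter part of a bar marks transcripts found in the 72 h desiccated library alone. Higher transcripts outnumber lower ones in 5 of the 6 pairs, and after resubmergence from 72 h 2713 are higher and 4958 lower, of which 1342 are the lighter part.

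The second question of the series is what changes within 1 h of return to seawater. Transcript c26385_g1_i1 (2487 nt, 30.8% GC) fell in each of the 3 periods and was the 1 transcript of 66046 that passed the test. It had 10086, 1277 and 3008 counts in the libraries desiccated for 24, 36 and 72 h and 1, 0 and 0 counts after resubmergence, against 1162 in the control. The fall at 24 h was 10318-fold (95% counting interval 1851 to 407560). Against a floor of 3 counts those at 36 and 72 h were 456-fold and 1316-fold, with lower 95% counting limits of 370 and 1069.5. Its log2 change was -13.48 with an adjusted p of 0.0118 in edgeR's quasi-likelihood test with the drying period as a block, lower in 3 of 3 periods. Transcript c29430_g1_i1 (2507 nt, 27.0% GC) had 4012, 539 and 1283 counts in the desiccated libraries, 0 counts in the 3 resubmerged libraries and 432 in the control. Against the floor of 3 counts it was 1368, 192 and 561-fold lower, with lower 95% counting limits of 1112, 156 and 456. It did not pass the test (adjusted p 0.149). The fitted log2 changes of both depend on how 0 counts are handled and are no bounds.

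On the higher side, c30183_g1_i1 (1125 nt, 59.8% GC) went from 2 to 91 counts after 24 h, from 2 to 5293 after 36 h and from 16 to 342 after 72 h, ratios of 44.5 (11.96 to 373), 2471 (684 to 20412) and 16.3 (9.89 to 28.8). Transcript c33674_g1_i2 (1630 nt, 62.1% GC) went from 65 to 1606, from 136 to 56039 and from 215 to 3849 counts, ratios of 24.2 (18.8 to 31.4), 385 (325 to 459) and 13.6 (11.9 to 15.7). Both had an adjusted p of 0.153 in the same edgeR test. In the control they had 44 and 775 counts.

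The test called 1 transcript lower and 0 higher, while 13708 transcripts had an unadjusted p under 0.05, 7794 higher and 5914 lower. Evenly spread p-values would give 3302, but transcripts are not independent. The 13708 became 8813 with the GC trend of each library removed, 8615 with the trend fitted on all transcripts, 7354 without the 24 h pair, 9152 without the 36 h pair and 15227 without the 72 h pair. DESeq2 called 6844 transcripts, 4312 higher and 2532 lower. The 1 call ended with limma-voom (0 calls, 16190 transcripts at an unadjusted p under 0.05), without the drying period as a block (adjusted p of c26385_g1_i1 0.172), without the 24 h pair (0.0613), without the 72 h pair (0.0580), without the 72 h desiccated library (0.0606), and with a trend on GC content removed from each library (0.140, or 0.0478 and still called when the trend was fitted on all transcripts). Without the 36 h pair 35 transcripts passed, 12 higher and 23 lower. On simulated counts with the fitted spread the test recovered 33% of transcripts changed 4-fold and 94% of those changed 16-fold. The simulation gave each transcript the trend's spread for its level and the same fold in each period. With changed transcripts also drawn only from those well above the count filter, it can overstate recovery. In the real libraries c29430_g1_i1, at least 192-fold lower in each period, was not called.

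By the 4-fold rule, 3642 transcripts were higher and 2176 lower after resubmergence from 24 h, 8458 higher and 4635 lower from 36 h, and 2713 higher and 4958 lower from 72 h. Of the 4958, 1342 belonged to the set found in the 72 h desiccated library alone, and 3616 remained without that set. In all 3 periods 473 transcripts in 409 genes were at least 4-fold higher and 154 in 130 genes at least 4-fold lower, where simulated unchanged libraries gave 90.8 and 88.8 and independent lists would share 19.2 and 11.5. With the GC trend of each library removed the 473 and 154 became 378 and 115. The simulated spread came from the model without the period block and holds differences between periods, so 90.8 and 88.8 may be too high. Pearson's r of the log2 ratios across transcripts was 0.46 between 24 and 36 h, 0.24 between 24 and 72 h and 0.25 between 36 and 72 h, and 0.27, 0.13 and 0.20 with the GC trend removed. These 3 comparisons share no library.

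The GC content of a transcript went with its ratio between resubmerged and desiccated libraries, a relation examined after the data were seen. The log2 ratio had slopes of 1.02, 1.05 and 0.65 per 10 points of GC after 24, 36 and 72 h, with a mean of 0.91 ± 0.22 (SD, n = 3) and an exact two-sided sign permutation p of 0.25, which is the smallest that 3 periods can give. Without the transcripts found in the 72 h desiccated library alone the mean slope was 0.85 and the 72 h slope 0.31. The bands of GC content leave out the 1342 transcripts found in the 72 h desiccated library alone. Among the 7681 other transcripts of 65% GC or more, the median log2 ratio was 1.29, 1.77 and 0.66 in the 3 periods, and among the 25298 others of 45 to 55% GC it was -0.73, -0.64 and -0.11, or -0.48, -0.26 and 0.10 with 1 transcript per assembled gene, which turns the direction at 72 h. The 138 others under 35% GC had medians of -2.50, -1.66 and 0.00, at percentiles 0, 0 and 36.7 of 10000 random lists matched on mean expression, and all 160 transcripts under 35% GC had medians of -2.02, -1.56 and -0.17. Transcripts under 40% GC took 2.58% of the counts in the control (Wilson 95% interval 2.57 to 2.58), 9.14% (9.13 to 9.14), 5.42% (5.42 to 5.42) and 2.21% (2.20 to 2.21) after 24, 36 and 72 h of desiccation, and 1.69% (1.69 to 1.69), 1.51% (1.51 to 1.52) and 1.86% (1.86 to 1.87) after resubmergence.

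**Figure D3:**
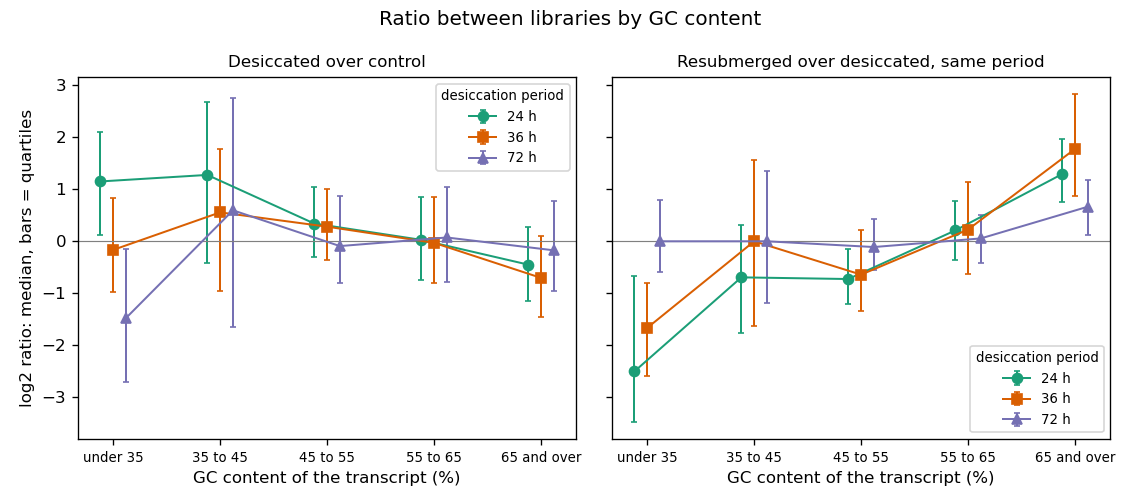
Median log2 ratio (points, with bars for the quartiles over transcripts) in 5 bands of transcript GC content, for desiccated over control (left) and resubmerged over desiccated of the same period (right), without the transcripts found in the 72 h desiccated library alone. After resubmergence the band of 65% and over lies at 1.29, 1.77 and 0.66 in the 3 periods, and the band under 35% at -2.50, -1.66 and 0.00.

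The libraries resubmerged for 1 h were also set against the control, which asks how far transcript levels were from those of thalli that never dried. Of the 2593 transcripts higher than the control in all 3 desiccated libraries, 78.1% were still at least 4-fold higher after resubmergence from 24 h, 58.9% from 36 h and 54.8% from 72 h, and 9.10%, 23.1% and 28.4% were within 2-fold of the control. Of the 1201 transcripts lower in all 3, 75.8%, 27.98% and 55.5% were still at least 4-fold lower and 8.24%, 44.5% and 14.8% were within 2-fold. With 1 transcript per assembled gene the order at 36 h turned, with 43.4% of 542 still at least 4-fold lower and 30.8% within 2-fold, and 13.9% of the 1074 higher ones were within 2-fold after 24 h. Both sets were selected against the same control, and unchanged libraries simulated with that selection gave 67.4%, 68.1% and 67.7% still higher (13.4%, 13.2% and 13.02% within 2-fold) and 51.9%, 52.7% and 53.0% still lower (22.8%, 21.9% and 21.7% within 2-fold), so these shares do not measure persistence by themselves. Against the control, 7777 transcripts were at least 4-fold higher and 4445 lower in the library resubmerged after 24 h, 7618 and 1817 after 36 h, and 5719 and 2175 after 72 h. In all 3 resubmerged libraries 1969 transcripts were higher and 433 lower, where simulated unchanged libraries that share 1 simulated control gave 1081 and 473. In the edgeR test of the 3 resubmerged libraries against the control 0 transcripts were called, with a smallest adjusted p of 0.465. An unadjusted p under 0.05 was found for 7074, DESeq2 called 2041 (1791 higher and 250 lower) and limma-voom called 0.

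Sets of transcripts present in some libraries and absent from others parted the libraries in several ways. A transcript was taken as on where it had at least 50 counts in each library of a set and at least 20 times the share of counts of any library outside it, a rule set after the data were seen. The 72 h desiccated library alone held 1710 such transcripts in 1077 genes, which took 1.45% of its counts and had a median GC of 43.8%, against 56.8% for all transcripts past the filter. The library resubmerged after 36 h alone held 93 transcripts in 72 genes with 3.08% of its counts, and the other libraries held 4 to 30 each. Splitting the control and the library resubmerged after 72 h from the other 5 libraries gave 269 transcripts, 265 of them off in this pair (74 genes) and 4 on (2 genes). Splitting the control from the rest gave 58, 36 of them off in it (10 genes) and 22 on (20 genes). The 3 desiccated libraries against the rest gave 6 in 6 genes, and the 3 resubmerged libraries 3 in 3 genes. A split by period, both 24 h libraries against the other 5, gave 39 transcripts off in them (13 genes) and 3 on (3 genes).

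Leaving the library resubmerged after 36 h out of the definition, 303 transcripts in 89 genes were on in the 3 desiccated libraries and the one resubmerged after 24 h, and off in the control and the one resubmerged after 72 h, while 41 transcripts in 23 genes showed the opposite. In the library resubmerged after 36 h the 303 stood at a median of 0.660 of their level in the libraries where they are on, and the 41 at 0.372. All 303 are among the 2593 transcripts higher than the control in all 3 desiccated libraries and all 41 among the 1201 lower ones.

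**Figure D4:**
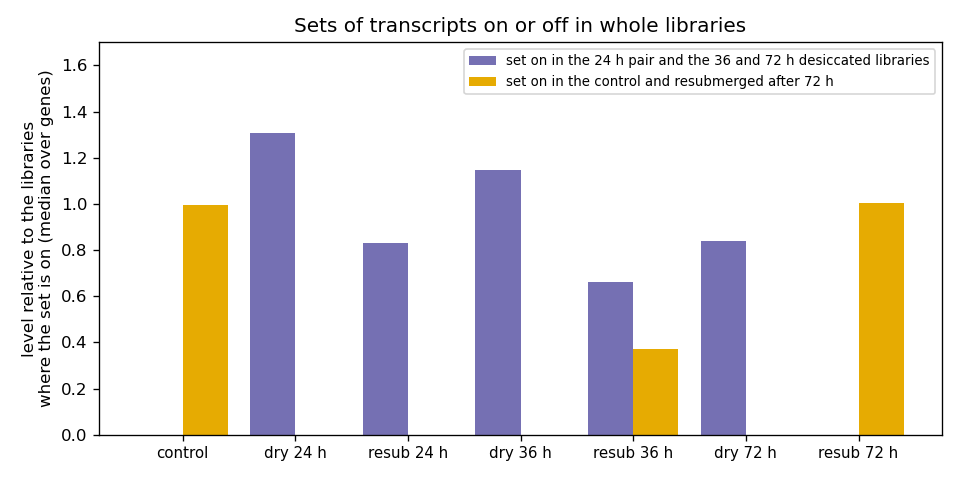
Median level over assembled genes of the 303 transcripts on in the desiccated libraries and the one resubmerged after 24 h (purple) and of the 41 transcripts on in the control and the one resubmerged after 72 h (yellow), each relative to the libraries where it is on. In the library resubmerged after 36 h both sets are present, at 0.660 and 0.372.

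The authors' deposited tables of pairwise comparisons give their own adjusted p-values for 1 library against 1. At an adjusted p under 0.05 the authors' deposited tables hold 358 transcripts higher and 315 lower after 24 h of desiccation than in the control, 352 higher and 129 lower after 36 h, and 575 higher and 73 lower after 72 h, of which 308 are in the set found in the 72 h desiccated library alone. For resubmergence the authors' deposited tables hold 9 higher and 59 lower after 24 h, 93 higher and 11 lower after 36 h, and 113 higher and 1288 lower after 72 h, 687 of the 72 h calls from the same set. Each of these calls was also at least 4-fold apart in the ratios computed here. Both use the same counts, and the smallest finite fold among the authors' calls was 5.77, so this is no independent check. In the authors' deposited tables c26385_g1_i1 has adjusted p-values of 3.45e-12, 0.00359 and 9.32e-16 for resubmergence after 24, 36 and 72 h. The tables of the 24 h comparison with the control were deposited in both orders, and their p-values are equal in all 137594 transcripts. These values compare libraries and not conditions.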

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

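The tests of other splits, of the GC trend, of a single source, of a response that grows with time, of a mixture of thalli and of a desiccation response in the on or off sets were chosen only after their results were seen, as were the look at the sets of other single libraries, the exchange of degrees of freedom and the comparison with other transcripts under 35% GC, and those of another organism and of alleles were fixed before.

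Among transcripts at least 4-fold apart after resubmergence, 35.4% were higher in the 72 h pair, against 62.6% in the 24 h pair and 64.6% in the 36 h pair, and this difference between periods was not tested. It depends on the threshold, since at 2-fold the shares were 50.1%, 50.9% and 53.9%, and at 8-fold 21.3%, 62.0% and 74.9%. Without the transcripts found in the 72 h desiccated library alone the 72 h share at 4-fold was 42.9%. The median log2 ratio to the control of the 138 transcripts under 35% GC that were not found in the 72 h desiccated library alone was 1.15 after 24 h of desiccation, -0.16 after 36 h and -1.47 after 72 h, at percentiles 100, 0.71 and 0 of random lists, a difference between periods that was not tested. Over all 160 transcripts under 35% GC the medians were 0.86, 0.00 and -0.91. Among transcripts too low to enter the comparisons, 51190 had at least 1 count in the 72 h desiccated library, against 29250 in the control, the lowest, and 37769 to 40896 in the remaining libraries. At 38 to 46% GC these numbered 12106 in that library and 2695 to 4761 in the others.

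The call of 1 transcript for resubmergence was set against the other ways to split the 6 libraries into 3 and 3. As many calls came from 1 of the 10 splits, the real one, and the highest of the others gave 0. At an unadjusted p under 0.05 the real split gave 13708 transcripts (8813 with the GC trend removed, which was not run on the other splits), the highest of the others 7588, and the highest of those that also part all 3 pairs 2288. The 7588 came from a split that parts 1 pair, where the block leaves the contrast to the 36 h pair alone. Splits of that kind do not exchange the states in every pair, and they came in duplicates with equal numbers. Fewer than 10 splits part all 3 pairs, and even with 10 splits no share under 0.05 can be reached.

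Transcripts c26385_g1_i1, c29430_g1_i1 and c27924_g1_i1, the last named after its values were seen, had 27.0 to 32.7% GC and 0 or 1 count in each of the 3 resubmerged libraries. Removing each library's GC trend left the smallest of their 9 log2 falls at 6.9998, from 7.49 before. They were selected for a level at least 20 times higher where on, so a large fall was bound to remain and does not decide on that trend as the cause. Part of the trend also stayed at this GC content, with medians of -0.68 and -0.94 after resubmergence from 24 and 36 h under 35% GC. With the trend removed, the call of c26385_g1_i1 ended. Its log2 change went from -13.48 to -12.60, its quasi-likelihood dispersion from 0.523 to 0.586 and its adjusted p from 0.0118 to 0.140. The denominator degrees of freedom fell from 6.87 to 5.33 and account for most of the rise in the unadjusted p. The new F of 378.2 with the former degrees of freedom gives an unadjusted p of 2.94e-07 against 3.72e-06. A trend fitted on all transcripts, with 5.34 degrees of freedom and an F of 699.5, left the call at 0.0478. Between these 2 removals, with nearly the same degrees of freedom, F therefore decided whether the call stayed. Over the control and the 3 desiccated libraries the ratio of the other 2 transcripts to c26385_g1_i1 varied by a median of 1.16-fold while c26385_g1_i1 itself moved 8.08-fold (1.36-fold and 3.94-fold with the GC trend removed), and that of 47 other transcripts under 35% GC by a median of 9.10-fold and at least 4.58-fold, in line with a single source, such as another organism or a replicon, that was lost on return to autoclaved seawater. This rests on 2 transcripts, and joint regulation by the alga, which was not tested, stays open.

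The 72 h desiccated library held 1710 transcripts in 1077 genes found there alone, against 4 to 93 transcripts for the other single libraries, with a median GC of 43.8% against 56.8% for all transcripts past the filter. Their summed level was 14506 CPM against 68.5 to 250 in the others, and 1.72% of that level after resubmergence from 72 h. Of the 1710, 2.22% lay in an assembled gene with a transcript expressed in at least 4 of the other 6 libraries, against 42.4% of other transcripts 4-fold higher in that library and matched on count, but the sets of the other single libraries gave 0 to 17.4%, so selection for absence elsewhere can itself give a low share. Their sum at 36 h was 1.54 times that at 24 h and 1.598 times that in the control, but the set was selected for a low level at 36 h, so these ratios do not exclude a drying response that grows with time. Reads from another organism and such a response cannot be told apart by these tests.

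The control and the library resubmerged after 72 h parted from the other libraries by 269 on or off transcripts, against 6 for the desiccated libraries, 58 for the control and 3 for the resubmerged libraries against the rest, but a drying response that is kept 1 h after 24 and 36 h and lost after 72 h gives the same sets, so these counts do not exclude it. Of the 269, 265 lie in 74 genes, while the control's 58 are 36 in 10 genes and 22 in 20. Both 24 h libraries parted from the rest by 39 transcripts in 13 genes off there and 3 in 3 genes on, a split by period and not by state. In the library resubmerged after 36 h the median levels of both sets, 0.660 (quartiles 0.426 to 0.956) and 0.372 (0.230 to 0.760), summed to 1.03 (95% bootstrap interval 0.868 to 1.31 over genes), near the 1 that a mixture of thalli of 2 genotypes would give. A mixture also needs 1 share within each set, while the quartile ranges there, 1.02 and 1.51 in log2, were wider than in libraries where the sets are on (0.62 to 0.92 for the first set and 0.89 for the second), so a mixture and a drying response cannot be told apart by these tests. No assembled gene held transcripts of both sets (0 genes, with a random median of 0 and a random highest of 2), which leaves alleles of the same genes open, and an organism associated with some thalli was not tested. If genotypes differ, part of the 2593 and 1201 transcripts that differ from the control in all 3 desiccated libraries may come from genotypes and not from drying. The 303 and 41 are part of the 2593 and 1201 by their definition.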

How the results depend on the processing

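The GC trend removals, the tests on 1 transcript per assembled gene, and those without the 72 h desiccated library or its own transcripts were chosen after seeing the data. The 1 call for resubmergence became 6844 with DESeq2, 8111 without a count filter, 2 with 1 transcript per assembled gene (c26385_g1_i1 and c8089_g1_i1) and 0 with limma-voom, with no replicate block, with all 7 libraries and no replicate block, with the GC trend removed and without the 72 h desiccated library. Leaving out each drying period gave 0 to 35 calls. It stayed at 1 under the other 7 alternatives, among them the GC trend fitted on all transcripts. The adjusted p of c26385_g1_i1 ranged from 1.42e-62 to 0.174 over these settings. The 0 calls for desiccation became 3403 with DESeq2 and those for resubmerged against control 2041, and both stayed at 0 under their other 16 alternatives. With the GC trend removed, fewer denominator degrees of freedom account for most of the rise in the unadjusted p of c26385_g1_i1. Between the 2 removals of that trend its F decided whether the call stayed. Without a count filter those of c26385_g1_i1 went from 6.87 to 274400 while its F fell from 437.8 to 302.5. Its smaller p there therefore comes from the degrees of freedom. Whether this also gave the 8111 calls, and the cause of the other differences, was not tested. The periods pair the libraries by the design of the authors' tables, and without that block 13004 transcripts had an unadjusted p under 0.05.

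Numbers of transcripts at least 4-fold apart follow in the order desiccated 24, 36 and 72 h against control, then resubmerged against desiccated at 24, 36 and 72 h. They were 6547, 5303, 6498, 2355, 7219 and 2583 with a mean count of at least 100, where fewer transcripts were compared, 26052, 26427, 30551, 24558, 33050 and 19049 at 2-fold, and 5069, 3942, 6887, 1870, 5146 and 4023 at 8-fold. Without a filter 28888 were apart after 72 h of desiccation, 9354 after resubmergence from 24 h and 21738 from 72 h, and a prior count of 10 left 3448 after resubmergence from 24 h. Totals under all other alternatives stayed within 1.5 times, but 3 counts by direction moved more: the 2713 higher from 72 h fell to 1362 with a prior count of 10, the 2176 lower from 24 h to 1339 with the GC trend removed, and without a filter the 3954 lower after 36 h of desiccation became 6089. In the authors' deposited tables an adjusted p under 0.01 left 41 of 68 calls for resubmergence from 24 h, 45 of 104 from 36 h, 358 of 673 for 24 h of desiccation in either order, 303 of 481 for 36 h and 363 of 648 for 72 h. The 72 alternative log2 ratios of the transcripts named kept their direction.

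Alternatives set before the data were examined that need product names were not run: transcripts with a named product alone, counts summed by product, transcripts without bacterial best hits, and all tests of gene lists. Those for tables without counts had nothing to apply to. Depth limits ratios of transcripts at 0 to 3 counts to bounds or wide intervals.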

Other observations

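All transcripts in this part were chosen after their values were seen, and no explanation of them was tested. The library resubmerged after 36 h held c34542_g1_i1 (3213 nt, 43.8% GC) at 806512 counts, against 17 to 141 counts in the other 6 libraries. Transcript c34485_g1_i2 had 238821 counts there against 7 to 49 elsewhere, c33627_g2_i1, at 25.5% GC, had 215200 against 8 to 50, and c34654_g2_i1, at 58.2% GC, had 193638 against 1 to 22. The 93 transcripts found in that library alone summed to 2619662 counts. Of these 93, 7.53% lay in an assembled gene expressed in at least 4 of the other libraries.

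Transcript c16710_g1_i1 had 265914 counts in the control, 407263 in the library resubmerged after 36 h and 467766 in the one resubmerged after 72 h. It had 75, 121 and 31 counts after 24, 36 and 72 h of desiccation and 41 counts after resubmergence from 24 h.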
